A study of Cunninghamia lanceolata with 12 samples.

How the data were processed

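Messenger RNA was sequenced from roots of Chinese fir (Cunninghamia lanceolata), a conifer grown for timber in southern China. Cuttings of 1 clone, aged 1 year, had grown for 6 months in sand in a greenhouse before fertilizer was given. Roots were collected 80 h later, per the labels' protocols. The 12 libraries form 4 groups of 3: an unfertilized control, nitrogen, phosphorus, and nitrogen with phosphorus (called the mixture below). The labels' protocols give a fertilizer concentration of 0.7% for nitrogen or phosphate and do not state separately what the mixture contained. The series' design text calls the 3 libraries of a group biological repeats. Poly(A) RNA was selected and sequenced as paired ends, per the labels' protocols.

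The deposited table gives 1 value per library for 74288 genes, in TPM, a transcript abundance scaled to a fixed total per library. The unit is read from the values, since no header names it. The values have 2 decimals, are never negative, and sum to between 986619 and 993291 in each library. Each library was therefore read as scaled to one total before deposit, and what remains of the full TPM scale was not analysed here. The submitters' processing notes name cutadapt, FastQC, Salmon and edgeR, with no version or order. The steps between reads and values are otherwise not given in the sources used here. The gene identifiers have the form that the Trinity assembler gives (a component, then a gene within it), so the reference appears to be an assembly made from reads. No genome build, chromosome position, gene name or description is paired with the identifiers in the files used here. Genes are therefore reported by identifier, and no statement is made on what any of them encodes. The 19 gene lists fixed beforehand could not be tested for the same reason.

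TPM values keep no record of sequencing depth, so the depth of each library is unknown and no counting interval or detection limit is given. Low values are the least reliable. A value of 0 means only that a gene is listed at 0. Because TPM is a share of a fixed total, a gene group that takes a larger share lowers all others. Reads that match several contigs of one assembled component can be divided between them by the quantification, so contigs of one component are not independent measurements.

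Values were analysed as log2(TPM + 1), which understates the change of genes near or under 1 TPM. Genes with at least 1 TPM in at least 3 libraries were tested, which kept 63161 genes and left out 11127. One linear model with a mean for each group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, using an abundance-dependent prior variance. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are log2 differences with the model's standard error (SE). The comparisons were each fertilizer group with control, the fertilizer groups with each other, the nitrogen by phosphorus interaction, and an F test over the 4 groups. The planned count test was not used, because the table holds no counts and TPM gives no whole reads. The test of gene sets was limma's fry, which asks whether the genes of a set move, on balance, in one direction. Correlations between libraries are across genes, which are not independent replicates.

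Named genes followed a rule fixed before the data were examined. For identifiers without names it takes the 2 largest rises and 2 largest falls per comparison, among genes past the threshold whose 2 groups do not overlap and whose mean TPM is above the median of the genes tested (1.71 TPM). Only comparisons with called genes can name any. Any other identifier given was chosen after its values were seen.

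The fit was tested on simulated data with the real means and spreads, in 10 simulations of 63161 genes with 200 changed genes each. For the mixture against control, 3.50% of genes changed by 1 log2 unit were called, 57.1% of those changed by 2, and 82.8% of those changed by 3. The changed genes were drawn only from those with a mean level, on the log2 scale, of about 5 TPM or more. These rates therefore do not describe less abundant genes, and the median of all genes tested was 1.71 TPM. Of the unchanged genes, 0.00858% were called. The simulated genes and libraries were drawn independently, within groups and between them, without the resemblance of libraries across groups described below. In the real libraries, 1 regrouping of nitrogen and phosphorus called 2561 genes. The simulated share of unchanged genes that were called therefore need not hold for these data. Tests of single values over libraries enumerated all 15400 ways to divide 12 libraries into 4 groups of 3. No batch or date is given in the labels, so within-batch values could not be formed.

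The replicate numbers 1 to 3 recur in every group, and the libraries were not treated as paired. No 2 library columns were identical, and the largest Pearson correlation of log2 values between libraries was 0.880.

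Alternatives fixed before the data were examined were other scalings between libraries, limma without the abundance trend or with library weights, other filters and pseudocounts, a fit to the compared groups alone, the replicate number as a block, a fold threshold, and leaving out each library. Summing TPM over each Trinity component and leaving out 3 libraries that resemble one another were added after the data were seen.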

Results

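The root transcriptome was measured in 12 libraries of clonal Chinese fir cuttings, with 3 libraries each for control, nitrogen, phosphorus and the mixture. Between 35445 and 49814 assembled genes reached 1 TPM in a library. The mean was 44703 ± 6148 genes (SD, n = 3) in control, 41322 ± 1334 (SD, n = 3) in nitrogen, 39316 ± 3378 (SD, n = 3) in phosphorus and 39837 ± 2276 (SD, n = 3) in the mixture. The groups did not differ in this number by more than the spread between libraries (exact permutation p = 0.334). Sequencing depth is unknown for all libraries.

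A small set of very abundant transcripts moved together between libraries. The 10 genes with the highest mean level held 1.5% of the summed TPM in control replicate 3 and 32.8% in phosphorus replicate 2. Each of the 10 was lowest and highest in those same libraries. With the 10 most abundant genes of each library itself, the shares were 4.99% in control replicate 3 and 32.8% in phosphorus replicate 2. Choosing the 10 genes by mean TPM favours genes that are high in the same libraries, which the tests below do not allow for. Over the 12 libraries and the 45 pairs of these genes, the lowest Pearson's r of log2 levels was 0.974 and the lowest Spearman's rho 0.895 (permutation test, largest adjusted p 2e-05 and 0.00028). Without the 2 libraries farthest from the median, the lowest r was 0.943. The most abundant, TRINITY_DN57384_c0_g4, ranged from 2984 to 46860 TPM. This gene was singled out after its values were seen. The share averaged 9.08% ± 9.20 (SD, n = 3) in control, 9.98% ± 0.74 (SD, n = 3) in nitrogen, 22.0% ± 11.9 (SD, n = 3) in phosphorus and 6.04% ± 4.94 (SD, n = 3) in the mixture. The 4 groups did not differ in it beyond chance (exact permutation p = 0.145). Within control alone it ran from 1.5% to 19.3%.

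**Figure D1:**
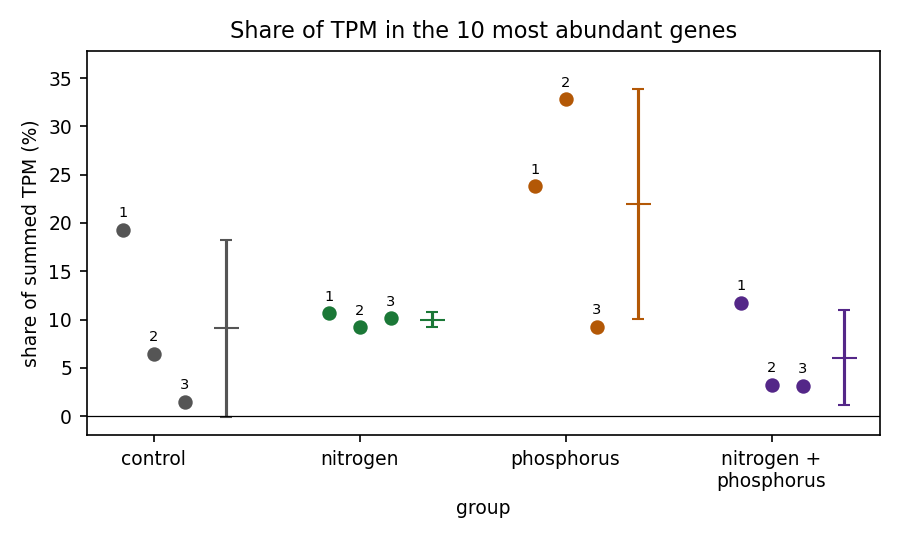
Share of the summed TPM (%) held by the 10 genes with the highest mean TPM, for each library by group. Points are libraries with their replicate number, and bars are the mean ± SD of 3 libraries; the share runs from 1.5% in control replicate 3 to 32.8% in phosphorus replicate 2, and the groups overlap.

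Libraries of one group resembled each other little more than libraries of different groups. Spearman's rho over the genes tested averaged 0.670 for the 12 pairs within a group and 0.658 for the 54 pairs between groups, a difference no larger than other groupings of the libraries gave (exact permutation p = 0.186, one-sided). All 6 of the highest correlations joined libraries of different groups, which is also the more frequent kind of pair (54 against 12). The closest pair was control replicate 3 and phosphorus replicate 3 (rho = 0.762), followed by nitrogen replicate 3 and phosphorus replicate 1 (rho = 0.755). The lowest value, 0.55, was between phosphorus replicate 2 and mixture replicate 3.

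**Figure D2:**
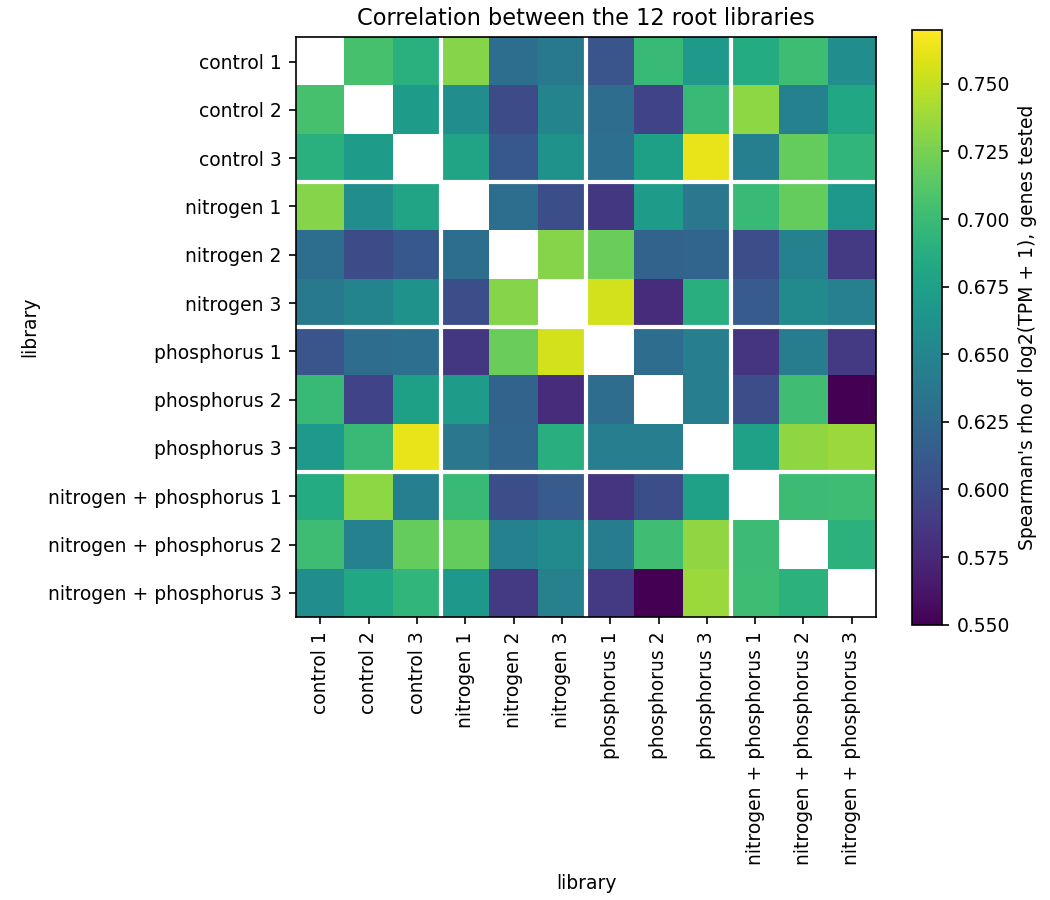
Spearman's rho of log2(TPM + 1) over the 63161 genes tested, for each pair of the 12 libraries; both axes list libraries by group and replicate, white lines separate the groups and the diagonal is blank. Nitrogen replicates 2 and 3 and phosphorus replicate 1 form a block of high values that crosses a group boundary, while the blocks within groups do not stand out.

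Nitrogen alone was compared with control to find its effect on root expression. No gene rose or fell past the threshold among 63161 tested with limma, and the smallest adjusted p was 0.529. At an unadjusted p under 0.05 there were 4502 genes, and up to 5575 when the same 6 libraries were regrouped into other sets of 3 against 3. Of the 9 other splits, 1 gave as many or more. The 95% interval of the log2 change had a median half-width of 1.21, so most changes of 2-fold in either direction were within the error. That interval lay entirely between -1 and 1 for 10838 genes, and among the 11782 genes with a mean of at least 10 TPM it did so for 54.8%. Library weights in limma also gave 0 genes. Without nitrogen replicates 2 and 3 and phosphorus replicate 1, the 3 libraries that resembled one another, 23 genes passed, with the 1 remaining nitrogen library assumed to vary like the others. The median log2 change over all genes was -0.14, and -0.04 after median-of-ratios scaling.

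Phosphorus alone was compared with control in the same way. No gene passed the threshold with limma, with or without library weights, and the smallest adjusted p was 0.637. There were 4100 genes at an unadjusted p under 0.05, and up to 13271 when the same 6 libraries were regrouped. Of the 9 other splits, 2 gave as many or more. The largest count came from setting control replicate 1 and phosphorus replicates 1 and 2 against the other libraries. Of the 6 libraries, these had the largest shares of TPM in the 10 most abundant genes (19.3%, 23.8% and 32.8%). The 95% interval lay between -1 and 1 for 6827 genes, and for 38% of those with a mean of at least 10 TPM. The median log2 change over all genes was -0.31, which became -0.02 after median-of-ratios scaling. Phosphorus replicate 2, whose 10 most abundant genes held 32.8% of the TPM, had the lowest scaling factor (0.592). Without the 3 libraries that resembled one another, 13 genes passed.

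A small set of root genes passed the threshold between the mixture and control in the planned fit, though not in every alternative given below. Of 63161 genes tested, 31 were higher and 96 were lower in the mixture (limma, adjusted p under 0.05). The 31 genes rose by a median of 2.61 on the log2 scale, and the 96 fell by a median of 2.10. The median of their mean levels was 36.3 TPM for the risen and 36.4 TPM for the fallen genes, against 1.71 TPM for all genes tested. The called genes lay in 118 Trinity components, of which 9 held 2 or more of them, against at most 5 in 1000 random draws of 127 tested genes matched on mean TPM, though not on the size of the component; this matching was chosen after the calls were seen.

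The largest rise was that of TRINITY_DN62640_c0_g2, which was at 0.48 ± 0.30 TPM (SD, n = 3) in control and 50.8 ± 42.0 TPM (SD, n = 3) in the mixture (log2 change 4.86, SE 0.825, limma adjusted p = 0.0407). In nitrogen it was at 17.6, 13.6 and 0.46 TPM, and in phosphorus at 0.67 to 4.73 TPM. TRINITY_DN58414_c1_g5 was at 6.98 ± 6.78 TPM (SD, n = 3) in control and 107 ± 43.1 TPM (SD, n = 3) in the mixture (log2 change 4.0, SE 0.588, limma adjusted p = 0.0316). Its level was 28.0 ± 14.8 TPM (SD, n = 3) in nitrogen and 5.43 ± 2.72 TPM (SD, n = 3) in phosphorus.

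The largest falls were those of TRINITY_DN64216_c1_g2 and TRINITY_DN57365_c0_g6. TRINITY_DN64216_c1_g2 was at 13.9 ± 3.44 TPM (SD, n = 3) in control, and in the mixture it was listed at 0 in 2 libraries and at 0.88 TPM in the other (log2 change -3.56, SE 0.622, limma adjusted p = 0.0418). It was at 3.91 ± 3.40 TPM (SD, n = 3) in nitrogen and 4.79 ± 3.51 TPM (SD, n = 3) in phosphorus. TRINITY_DN57365_c0_g6 went from 115 ± 58.3 TPM (SD, n = 3) in control to 10.1 ± 5.04 TPM (SD, n = 3) in the mixture (log2 change -3.32, SE 0.526, limma adjusted p = 0.0332). Nitrogen and phosphorus alone had intermediate levels, 43.1 ± 32.3 TPM (SD, n = 3) and 48.0 ± 12.3 TPM (SD, n = 3). No comparison of a single fertilizer with control passed the threshold for any of these 4 genes, and neither did the mixture against either single fertilizer. Leaving out any one of control replicates 1 and 2 or the 3 mixture libraries ended the call of each of the 4 genes. Over all 12 single libraries left out, the log2 changes ranged from 4.24 to 5.22 for TRINITY_DN62640_c0_g2, from 3.65 to 4.65 for TRINITY_DN58414_c1_g5, from -3.87 to -3.41 for TRINITY_DN64216_c1_g2 and from -3.85 to -3.01 for TRINITY_DN57365_c0_g6. The size for the 2 genes near 0 TPM in one group depended on the pseudocount: at 0.1 TPM the log2 change was 6.30 for TRINITY_DN62640_c0_g2 and -6.00 for TRINITY_DN64216_c1_g2, both past the threshold. TRINITY_DN62640_c0_g2 also missed the threshold without control replicate 3, nitrogen replicate 2 or phosphorus replicate 3, and TRINITY_DN64216_c1_g2 without control replicate 3 or nitrogen replicates 1 or 2. After each of the 3 other scalings, TRINITY_DN58414_c1_g5 stayed past the threshold and the other 3 genes did not. In all 24 alternatives, with these scalings among them, the log2 change of TRINITY_DN62640_c0_g2 was at least 4.24. That of TRINITY_DN64216_c1_g2 was -3.37 or lower, and that of TRINITY_DN57365_c0_g6 was -3.01 or lower. None of the 4 passed without the abundance trend, with the mixture and control libraries alone, or without the 3 libraries that resembled one another.

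The list depended on the model, the scaling and single libraries. No gene passed in limma without the abundance trend or with the mixture and control libraries alone, while library weights gave 482 genes and a minimum mean of 5 TPM gave 373. Against 31 higher and 96 lower, the calls were 27 higher and 19 lower after median-of-ratios scaling, 30 and 16 after trimmed-mean scaling and 31 and 30 after quantile normalization. Of the 127 genes, 33, 30 and 43 were among these calls, and 15, 14 and 15 of the 31 risen genes, while the direction was the same for all 127. Without the 3 libraries that resembled one another 4 were higher and 6 lower, with 3 of them among the 127. The number called was 3 without control replicate 1, 0 without control replicate 2, 78 without control replicate 3, 61 without nitrogen replicate 1, 28 without nitrogen replicate 2, 197 without phosphorus replicate 2, and 8, 5 and 4 without mixture replicates 1, 2 and 3.

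The 127 genes were then followed in the single fertilizer groups. Of the 31 risen genes, 30 had a higher mean in nitrogen than in control and 27 a higher mean in phosphorus, with median log2 changes of 1.47 and 0.40. Of the 96 fallen genes, 83 were lower in nitrogen and 96 in phosphorus, with median log2 changes of -0.40 and -0.84. After median-of-ratios scaling the medians of the risen genes were 1.59 in nitrogen and 0.80 in phosphorus, and those of the fallen genes -0.28 and -0.44. The genes were selected on the same 3 control libraries, which alone pulls these values in the observed direction. With genes ranked on 2 controls and measured against the control left out, the 31 leading risen genes were at 1.24, 1.39 and 0.50 in nitrogen and at 0.39, 0.55 and 0.02 in phosphorus. The 96 leading fallen genes were at -0.40, -0.49 and 0.15 in nitrogen and at -0.66, -0.91 and -0.29 in phosphorus. None of the 127 genes passed the threshold in either single fertilizer against control. This alone shows no difference between the mixture and the single fertilizers, since an adjusted p also depends on the other genes of its comparison. For example, TRINITY_DN27630_c0_g1 had a log2 change of -2.83 against control in nitrogen, phosphorus and the mixture alike.

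The same 127 genes were compared between nitrogen and phosphorus, whose libraries entered the selection through the shared estimate of the spread alone. That selection favours genes with a small spread within groups, these 2 among them, which can make the p-values of fry too small. Nitrogen was above phosphorus in 25 of the 31 risen genes, by a median of 0.94 on the log2 scale (limma's fry, p adjusted over the 2 sets 0.0408). It was also above phosphorus in 80 of the 96 fallen genes, by a median of 0.37 (limma's fry, p adjusted over the 2 sets 0.0408). Over libraries, the exact permutation p was 0.20 for the risen and 0.10 for the fallen genes, and 0.10 is the smallest that 3 against 3 can give. After median-of-ratios scaling the medians were 0.65 and 0.10, and neither set passed (limma's fry, adjusted p 0.568 and 0.743).

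**Figure D3:**
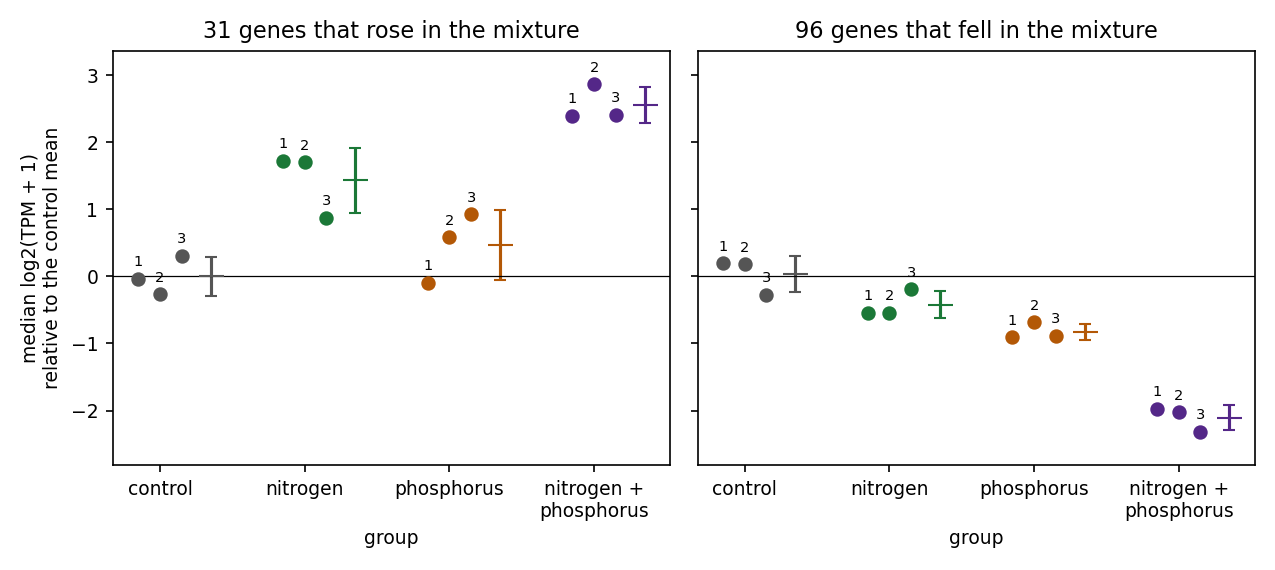
Median log2(TPM + 1), relative to the mean of the control libraries, of the 31 genes that rose and the 96 genes that fell in the mixture, for each library by group. Points are libraries with their replicate number and bars the mean ± SD of 3 libraries; control and mixture are apart because the genes were selected on them, and the means of nitrogen and phosphorus lie between, with phosphorus replicate 1 within the range of control and nitrogen replicate 3 closer to phosphorus than the other nitrogen libraries are for the risen genes.

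The mixture was compared with each single fertilizer to see what the other nutrient added. Against nitrogen, 4 genes were lower in the mixture and 0 were higher (limma, adjusted p under 0.05), with 5466 genes at an unadjusted p under 0.05, against up to 4309 when the 6 libraries were regrouped. All 4 were also among the 96 genes that fell against control. TRINITY_DN64282_c0_g1 was at 325 ± 30.2 TPM (SD, n = 3) in nitrogen and 44.2 ± 17.8 TPM (SD, n = 3) in the mixture (log2 change -2.93, SE 0.353, limma adjusted p = 0.0416). It was at 302 ± 76.8 TPM (SD, n = 3) in control and 111 ± 38.6 TPM (SD, n = 3) in phosphorus. TRINITY_DN63447_c0_g4 was at 55.2 ± 8.72 TPM (SD, n = 3) in nitrogen and 8.71 ± 2.15 TPM (SD, n = 3) in the mixture (log2 change -2.55, SE 0.314, limma adjusted p = 0.0416). Its control level was 30.7 ± 5.77 TPM (SD, n = 3) and its phosphorus level 18.6 ± 8.70 TPM (SD, n = 3). None of the 4 passed after median-of-ratios, trimmed-mean or quantile scaling, without the abundance trend, or with the mixture and nitrogen libraries alone, where no gene passed. Library weights gave 122 genes, a minimum mean of 5 TPM gave 135, and the fit without the 3 libraries that resembled one another gave 23, with none of the 4 among these 23. The count was 7 without control replicate 3, 1 without phosphorus replicate 2, and 0 without any one of control replicates 1 and 2, the 3 nitrogen libraries, phosphorus replicate 1 and the 3 mixture libraries. In these fits the log2 change ranged from -3.21 to -2.61 for TRINITY_DN64282_c0_g1, which also missed the threshold without phosphorus replicate 2. For TRINITY_DN63447_c0_g4 it ranged from -2.66 to -2.35. Over all 24 alternatives, with the other scalings among them, the ranges were -3.21 to -2.61 and -2.79 to -2.35.

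Against phosphorus, 0 genes passed in the mixture with limma, and 6074 genes were at an unadjusted p under 0.05, against up to 7098 when the 6 libraries were regrouped. Of the 9 other splits, 1 gave as many or more. The smallest adjusted p was 0.138. With library weights in limma the count was 869, of which 653 were higher in the mixture. That fit gave phosphorus replicate 1 a weight of 4.04 and the other phosphorus libraries weights of 0.465 and 0.494. Without nitrogen replicate 3 the count was 3, without phosphorus replicate 3 it was 5, and without the 3 libraries that resembled one another it was 7. The median log2 difference of all genes was 0.18, and -0.03 after median-of-ratios scaling.

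Nitrogen and phosphorus were also compared directly, and 0 genes passed with limma, with or without library weights. There were 3711 genes at an unadjusted p under 0.05, and up to 5659 when the 6 libraries were regrouped. Of the 9 other splits, 4 gave as many or more. The median log2 difference of all genes, nitrogen over phosphorus, was 0.19, and 0.01 after median-of-ratios scaling. Without the 3 libraries that resembled one another, 17 genes passed.

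The 4 groups form a factorial of 2 nutrients, so the mixture could be set against the sum of the single log2 changes. No gene had an interaction past the threshold in limma, with or without library weights, and the smallest adjusted p was 0.571. There were 5337 genes at an unadjusted p under 0.05. The median half-width of the 95% interval was 1.71 on the log2 scale. The count was 1 without phosphorus replicate 3 and 23 without the 3 libraries that resembled one another. The median interaction of all genes was 0.35 on the log2 scale, and 0.02 after median-of-ratios scaling. The F test over all 4 groups called 4 genes, all of them among those that fell in the mixture against control, and 2 of them also among those lower than in nitrogen. At an unadjusted p under 0.05 the F test had 5280 genes. It called 0 genes after each of the 3 other scalings and without the abundance trend, 465 with library weights, 8 with a minimum mean of 5 TPM and 33 without the 3 libraries that resembled one another. It called 2 genes without phosphorus replicate 1, 11 without nitrogen replicate 3, 13 without phosphorus replicate 3, and 0 without any one of control replicates 1 and 2, nitrogen replicates 1 and 2 and the 3 mixture libraries.

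Changes against control were compared between treatments, which share the control libraries. Since nitrogen alone and phosphorus alone called no gene, no call could be shared between the comparisons with control. Across genes, which are not independent replicates, the log2 changes of nitrogen and phosphorus correlated at r = 0.56, those of nitrogen and the mixture at 0.45 and those of phosphorus and the mixture at 0.41. Unchanged groups set against shared controls gave a simulated r of 0.50. The covariances were 0.238, 0.207 and 0.170, against 0.202 simulated. The simulated values already include the sharing of controls. The covariance differed from the simulated one by 0.0362 for nitrogen and phosphorus, 0.005 for nitrogen and the mixture, and -0.0314 for phosphorus and the mixture. The simulated values come from 20 simulations, and their spread is not given here. Whether these differences lie beyond that spread cannot be told. What the differences come from was not tested. With 3 controls no division of them keeps 2 libraries on each side, and the comparison was not made with separate controls.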

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

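The interaction test was chosen before the data were examined, and its adjustment over the 6 named genes afterwards. For 2 of these genes the estimated nitrogen effect was lower with phosphorus than without it, past the threshold over the 6 genes alone. TRINITY_DN63447_c0_g4 had a log2 change with nitrogen of 0.83 (SE 0.314) without phosphorus and -0.95 (SE 0.314) with it, an interaction of -1.78 (SE 0.445, limma adjusted p over the 6 genes 0.00846). TRINITY_DN64282_c0_g1 had 0.13 (SE 0.353) and -1.31 (SE 0.353), an interaction of -1.45 (SE 0.499, limma adjusted p over the 6 genes 0.0363). Both genes were named for a large mixture to nitrogen difference, which is part of the interaction, so the selection itself favours such values and they do not show that the effect differs. Neither passed when adjusted over all 63161 genes, where the smallest adjusted p was 0.571.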

How the results depend on the processing

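Summing TPM per Trinity component and leaving out the 3 libraries that resemble one another (nitrogen replicates 2 and 3, phosphorus replicate 1) were chosen after the data were seen. For the mixture against control the count of 127 genes became 46 with median-of-ratios scaling, 46 with trimmed-mean scaling, 61 with quantile normalization, 0 without the abundance trend, 482 with library weights, 373 with a mean of at least 5 TPM, 0 with the 2 compared groups alone, 55 components with summed TPM and 10 without the 3 libraries. With the replicate block it was 84, of which 71 were among the 127, and leaving out single libraries gave 0 to 197. The mixture against nitrogen, 4 genes, became 0 under each of the 3 scalings, without the trend and with the 2 groups alone, 122 with library weights, 135 with a mean of at least 5 TPM, 21 with the replicate block, 1 component with summed TPM and 23 without the 3 libraries, and 0 to 7 without single libraries. The F test over the 4 groups, 4 genes, became 0 under the 3 scalings and without the trend, 465 with library weights, 8 with a mean of at least 5 TPM, 33 without the 3 libraries, and 0 to 13 without single libraries. The mixture against phosphorus, 0 genes, became 869 with library weights, 7 without the 3 libraries and 0 to 5 without single libraries, 5 being the count without phosphorus replicate 3. Without the 3 libraries, which leaves nitrogen with 1 library assumed to vary like the others, nitrogen against control had 23 genes, phosphorus against control 13, nitrogen against phosphorus 17 and the interaction 23. Each of these 4 counts was otherwise 0 with all libraries and under each of the alternatives fixed beforehand, except that the interaction had 1 gene without phosphorus replicate 3; the single-library range was 0 to 0 for the other 3. Pseudocounts of 0.1 and 0.5, no filter, and a log2 change of at least 1 gave 148, 142, 118 and 127 genes for the mixture against control and 5, 5, 4 and 4 for the mixture against nitrogen. The 6 named genes kept their direction under all 24 alternatives each, with 9 to 16 of them past the threshold for the mixture against control and 8 and 9 for the mixture against nitrogen. Deviations from the group means correlated across genes at between -0.30 and 0.24 over the 18 pairs of same-numbered libraries, 7 of them over 0.1, and 4 of the 12 libraries correlated best with their own number, so the numbers do not pair the libraries; with the replicate block the F test gave 6 genes and the other 5 counts stayed at 0, and TRINITY_DN62640_c0_g2, TRINITY_DN64216_c1_g2 and TRINITY_DN57365_c0_g6 were not called. The planned count tests were not run, since TPM holds no counts, and no gene list could be tested. The fits to fewer libraries or genes differ by construction; for the other settings, apart from median-of-ratios scaling, the cause was not tested. Unknown depth leaves the counting error of each value unknown.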

Other observations

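The search for genes present in sets of 3 libraries, the comparison with other genes of like abundance, the tests of exchanged labels and of the most abundant genes, the splits of the 6 comparisons between groups, the relation within groups, and the counts of how calls ended were chosen only after the results were seen. A set of 315 genes, in 288 Trinity components, was at 5 TPM or more in nitrogen replicates 2 and 3 and phosphorus replicate 1 and at 0.5 TPM or less in each of the other 9 libraries. No other of the 220 sets of 3 libraries had more than 2 such genes. The 315 genes held 0.444%, 0.345% and 0.350% of the TPM in the 3 libraries, and at most 3.72e-05% in any of the other 9. The most abundant of them, TRINITY_DN18247_c0_g1, was at 311, 202 and 215 TPM in the 3 libraries and listed at 0 in the other 9.

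What the 315 genes come from is open, and no effect of fertilizer on them was tested, since the 3 libraries do not share a treatment. Another fir genotype could bring alleles of genes that the other libraries also hold. Of the 315, 17.1% shared a Trinity component with a gene detected in 3 or more of those libraries. The median was 66.0% in 10000 lists matched on abundance (5th percentile 61.6%, lowest 53.7%). Most of the 315 were thus not alleles placed in one component with a gene of the other libraries. Alleles or genes assembled in components of their own would give a low share too, so another genotype stays open. RNA of another organism may be the source: its genes should keep 1 ratio between libraries, and the median SD of their log2 ratios was 0.439, under the bound of 0.5 set beforehand, but other genes of like abundance gave 0.442, so this cannot be told apart from fir genes active in these plants alone. An exchange of the labels of nitrogen replicate 1 and phosphorus replicate 1 would put the 3 libraries in 1 group, but over the 31 genes that rose in the mixture nitrogen replicate 1 lay 0.804 (log2) above the highest phosphorus library, and phosphorus replicate 1 (-0.09) under the 3 nitrogen libraries (0.87 to 1.73). Over the 96 fallen genes nitrogen replicate 1 (-0.54) lay among the nitrogen and phosphorus replicate 1 (-0.91) beside the phosphorus libraries. These values cannot decide on an exchange, because the genes were called with a spread computed under the present labels. That favours genes that place each library with its labelled group. Each is also placed against only 2 other libraries per group, as far apart as 0.87 and 1.70 in nitrogen. Nitrogen and phosphorus were not shown to differ over these genes after the other scalings. Over all genes tested, nitrogen replicate 1 had rho of 0.672 and 0.638 with phosphorus replicates 2 and 3. With nitrogen replicates 2 and 3 it had 0.629 and 0.603. Phosphorus replicate 1 had 0.720 and 0.755 with nitrogen replicates 2 and 3, and 0.629 and 0.644 with the other phosphorus libraries. An exchange therefore stays open.

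The share of the 10 most abundant genes was not tied to a treatment (exact permutation p = 0.1449), which leaves a fertilizer effect open. Libraries of low complexity would have fewer genes at 1 TPM where the share is high. A larger share also lowers the TPM of all other genes, so such a relation could arise without low complexity too. Over the 12 libraries Spearman's rho was -0.329 (permutation p = 0.298, adjusted over 3 tests 0.298) and Pearson's r was -0.56 (permutation p = 0.0635, adjusted 0.185), and r of the deviations from the group means was -0.66 (exact permutation within groups, p = 0.123, adjusted 0.185). Without phosphorus replicates 1 and 2, the libraries farthest from the median share, r was -0.46 and rho -0.21. These values neither exclude low complexity nor show it.

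The 127 genes called between the mixture and control were tested against 2 technical explanations. The first was a shift of the TPM scale by a few abundant genes, which should remove their change. After median-of-ratios scaling their median absolute log2 change was 2.10, from 2.15 before. The scaling factors overlapped, at 0.886 to 1.316 in control and 0.983 to 1.136 in the mixture. Such factors could move the difference between the groups only slightly, so a large loss could hardly have occurred. The test shows only that a difference in scale between these groups accounts for little of the size of the change. The calls did depend on the scale, with 24.4% of them higher in the mixture before and 58.7% after. The count under quantile normalization was known when this test was written. The median change went from 2.61 (median SE 0.398) to 2.58 (median SE 0.392) for the 31 risen genes, of which 16 calls ended, and from -2.10 (median SE 0.328) to -2.04 (median SE 0.378) for the 96 fallen genes, of which 78 ended. Of the 16, 2 ended through the adjustment over all genes alone, 13 with a larger SE and no smaller change, and 1 with both a larger SE and a smaller change, and of the 78, 7 ended through the adjustment alone, 69 with both a larger SE and a smaller change, whose parts were not separated, and 2 with a smaller change alone. Of the 110 called genes with tested siblings, 77.3% kept their direction and at least 50% of their log2 change in the summed component, which argues against reads divided between contigs as the whole cause, while the fertilizer mixture itself and differences between single plants remain open.

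Other splits of the libraries were counted in the same fit. For the mixture against control, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 127 genes, and the highest other gave 0. For the mixture against nitrogen, 1 of 10 gave 4 genes and the highest other gave 0. With 10 splits the share cannot fall under 0.1. Nitrogen against control, phosphorus against control and the mixture against phosphorus had 0 genes in each of the 10 splits, and where the real count is 0 every split gives as many, which says nothing of chance. The same holds for nitrogen against phosphorus, with a real count of 0 and 10 of 10 splits, which had 2561 genes in the split that sets nitrogen replicates 2 and 3 and phosphorus replicate 1 against the other 3 libraries, a structure of the samples that crosses the treatments. For the interaction the real count of 0 also fixes the outcome at 100 of 100 splits of the 12 libraries, and the highest other gave 3190. For the F test over 4 groups 5 of 100 splits gave 4 genes or more, the highest 3038, so chance is not excluded.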
